A study of Mus musculus with 4 samples.

How the data were processed

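Liver RNA of C57BL/6 mice was hybridised to 4 Affymetrix Mouse Genome 430 2.0 arrays, 2 for wild-type (WT) mice and 2 for mice lacking Baf60a in the liver (Baf60a LKO). Per the labels, each array carried an independent pool of RNA, and the number of mice in a pool is not given in the sources used here. A replicate is therefore a pool, and p-values reflect the spread between pools, not between single mice. Samples were grouped by the genotype in their labels. The arrays hold no read depth.

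The deposited values are on the log2 scale, by their range, with 1 value per probe set and array. The submitters' processing notes name robust multi-array average (RMA), a method that corrects background, normalizes arrays by quantiles and summarises probes, and the packages affy and limma, with no versions. RMA compresses differences at low levels, so folds of dim genes can be understated. Detection calls were not analysed here. As a gauge of background, the 41 probe sets for bacterial transcripts had medians of 2.30 to 2.50 and 95th percentiles of 3.02 to 3.42 on the 4 arrays.

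Of 45101 probe sets, 64 controls were left out of the tests of genes, probe sets and lists, which leaves 45037. Only the fit that gives the Cre controls their p-values covers all 45101. The platform annotation gave 1 gene symbol to 34945 of these and several to 932, and it did not list 9160. Symbols were set against the RefSeq gene table of GRCm38.p6 by Entrez number, where 34741 probe sets matched and 204 kept the symbol as given. No genome build is named for the deposited values, so the RefSeq table served only for names and for which genes neighbour each other. Each gene was represented by the probe set with the highest mean over the 4 arrays, which gave 18193 genes. No filter on level was applied. Near-identical family members can share probes, so values of single Mup, Cyp2c, Saa and Gstp genes are uncertain.

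Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with defaults), 2-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. The fit had 2 residual degrees of freedom and 3.55 prior degrees of freedom. Errors beside log2 fold changes are standard errors of this fit (2 arrays per group). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

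Before the data were examined, 40 gene lists were written down, for bile acids, sterols, lipids, xenobiotic response, sex bias, clock, stress, inflammation and cell types. They held 717 members, of which 638 had a value, and 39 lists had the 5 measured members needed for a test. Lists were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 39 lists. The genes named in the text follow a rule of the same date. It takes Smarcd1 and its paralogs, the 10 largest falls and 10 largest rises past the threshold with non-overlapping groups and a gene name, a fixed set of bile acid and sterol genes, and up to 4 members of each list described. Of the fixed set, 10 had a value and 2 are not analysed here. Genes outside the rule are said to be chosen after their values were seen.

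The scripts were tested on simulated data for the comparison of Baf60a LKO with WT, with 18193 genes at the WT means, variances drawn from limma's prior and 200 genes changed. Of 68 genes changed by 1 on the log2 scale, 42.6% were recovered with the right sign, of 66 changed by 2, 90.9%, and of 66 changed by 4, 98.5%. Of the 165 calls, 11 were of unchanged genes. With the bile acid synthesis list shifted by -0.50, camera gave it an adjusted p of 6.64e-23 and called 0 of the other 38 lists, while camera with an estimated correlation gave it 0.317. The simulated genes varied independently of each other, and each with the same variance in both groups. In the real data the estimated correlation was, for example, 0.605 for cholesterol synthesis and 0.216 for CAR and PXR targets. The simulation therefore does not gauge false list calls among correlated genes. In the real data the difference between replicates had a standard deviation of 0.33 for WT and 0.21 for Baf60a LKO. Recovery and false gene calls under such unequal spread were not gauged either.

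The alternatives tried were 3 further normalizations (quantiles, cyclic loess, array medians subtracted), the brighter 50% of genes, the mean of a gene's probe sets, leaving out probe sets whose names end in _x_at or _s_at, a trended and robust eBayes, a replicate block, other thresholds and leaving out each array. Leaving out 1 array leaves a group with 1 pool, which is then assumed to vary like the other group.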

Results

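Livers of WT and Baf60a LKO mice were compared after 10 weeks of high-fat diet that began at 6 weeks of age, with tissue taken after an overnight fast. BAF60a, the product of Smarcd1, is a subunit of the SWI/SNF chromatin remodelling complex. Each group had 2 arrays, each with its own RNA pool. The median log2 value per array lay between 4.19 and 4.27. Over probe sets, which are not independent replicates, WT replicate 1 correlated with the other arrays at 0.987 to 0.991, and the other pairs at 0.993 to 0.996. The standard deviation of the difference between replicates was 0.33 for WT and 0.21 for Baf60a LKO on the log2 scale. For WT replicate 2 against Baf60a LKO replicates 1 and 2 it was 0.28 and 0.27, below that between the WT arrays.

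The targeted gene was read by 2 probe sets. On the brighter one, Smarcd1 stood at 5.62 and 5.88 in WT and at 5.34 and 5.30 in Baf60a LKO, a log2 fold change of -0.43 ± 0.14, which did not pass (limma, adjusted p = 0.410 over genes), and -0.28 with both probe sets averaged. The other lay near background in all arrays, with means of 2.87 in WT and 2.73 in Baf60a LKO. Whether either probe set lies in the deleted part of the gene is not known, so these values do not check the genotype. The paralog Smarcd2 differed by 0.03 ± 0.14, a sign that turned when the arrays were normalized again by quantiles or loess. Smarcd3 differed by -0.19 ± 0.13 (-0.07 without WT replicate 1 and -0.32 without WT replicate 2). None of the 28 measured SWI/SNF subunits passed over all genes or adjusted over the list alone. The largest differences among them were those of Ss18l1 (-0.84 ± 0.19, but 0.18 on the probe set used when _x_at and _s_at probe sets were left out), Bicral (0.78 ± 0.27) and Bcl7a (0.59 ± 0.29, with overlapping groups). Without WT replicate 1 the values of Bicral and Bcl7a were 0.40 and 0.19, and with averaged probe sets 0.31 and 0.07. Without WT replicate 2 Bcl7a was at 0.98. The list did not pass (camera, adjusted p = 0.663).

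The comparison of genotypes asks which liver genes differ when BAF60a is missing, and the study's title places the question in bile acid metabolism and cholesterol absorption. Hsd3b5, Hsd17b6 and Nr1i3 fell furthest in Baf60a LKO livers, and Gstp3 rose furthest. Hsd3b5, a steroid dehydrogenase gene, fell 80.2-fold (log2 fold change -6.33 ± 0.42, limma adjusted p = 0.0117), and Hsd17b6, of another steroid dehydrogenase family, fell 27.9-fold (log2 fold change -4.80, and -2.41 with its probe sets averaged). Nr1i3, which encodes the xenobiotic receptor CAR, fell 27.3-fold, from a mean of 11.2 to 6.46 (log2 fold change -4.77 ± 0.14, adjusted p = 0.000591). Serpina12, the gene of the adipokine vaspin, fell 24.2-fold (-4.60, and -2.65 with averaged probe sets), the major urinary protein gene Mup10 fell 24.2-fold, and the serpin locus Serpina4-ps1 fell 16.2-fold. The cytochrome P450 genes Cyp2c50, Cyp2c54 and Cyp2c37 fell 13.9-fold, 12.9-fold and 12.6-fold, and Slco1a4, an organic anion transporter gene, fell 13.4-fold.

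Among the rises, Gstp3, a glutathione S-transferase gene of the pi class, stood first, at 29.0-fold (log2 fold change 4.86 ± 0.12, adjusted p = 0.000427). The transcription factor gene Tcf24 rose at least 9.77-fold, from WT values of 3.44 and 3.30 that do not stand clear of background, and Akr1c18, an aldo-keto reductase gene, rose 9.39-fold. Hebp2 rose 6.87-fold (2.78, but 0.93 with averaged probe sets, adjusted p = 0.0764), Pcp4l1 6.11-fold, Arhgef16 4.99-fold and Calml4 4.22-fold. Saa2 and Saa1, acute phase proteins made by the liver, rose 6.79-fold and 4.47-fold, and Csad, an enzyme of taurine synthesis, rose 3.89-fold. Pcp4l1 is a direct neighbour of Nr1i3, and Tomm40l, the neighbour on the other side, rose 3.87-fold (adjusted p = 0.0107, chosen after its values were seen).

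In all, 88 of 18193 genes passed by limma with Benjamini-Hochberg adjustment, 43 higher and 45 lower in Baf60a LKO. The median fall was 4.79-fold and the median rise 2.68-fold, and 14 falls and 3 rises reached 8-fold. At an unadjusted p under 0.05 there were 1853 genes, where 910 are expected by chance. Over all 45037 probe sets, 84 passed, 30 higher and 54 lower, of which 8 are not in the table of names. Of the 34 called genes with more than 1 probe set, 17 had another probe set that moved at least 0.5 times as far the same way and 7 had one that moved the opposite way. The number of calls rested on all arrays: 0 genes passed by limma without WT replicate 1 (1630 at an unadjusted p under 0.05), 3 without WT replicate 2, 10 without Baf60a LKO replicate 1 and 17 without Baf60a LKO replicate 2. With a replicate block 19 passed, 5 higher and 14 lower, while all 88 kept an unadjusted p under 0.05 by limma. An array left out or a block added leaves fewer degrees of freedom. A lower count alone therefore does not show that the differences rest on single arrays. With array medians subtracted, 154 genes passed, 91 higher and 63 lower, and 142 passed after cyclic loess and 216 with a trended and robust eBayes.

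**Figure D1:**
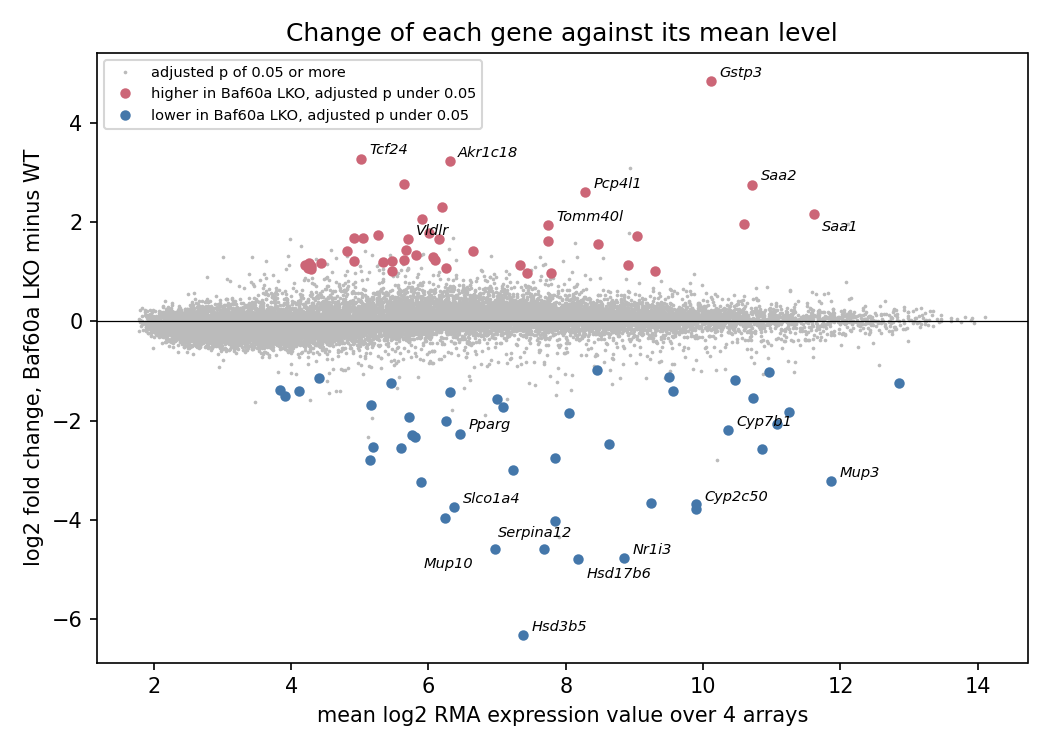
Each point is 1 of 18193 genes, with its mean log2 RMA value over the 4 arrays on the x axis and its log2 fold change, Baf60a LKO minus WT, on the y axis. Coloured points are the 43 genes higher and 45 lower at adjusted p under 0.05 by limma, from Gstp3 at 4.86 to Hsd3b5 at -6.33.

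Genes of bile acid synthesis lay lower in Baf60a LKO livers, led by the oxysterol hydroxylase Cyp7b1. Cyp7b1 fell 4.57-fold (log2 fold change -2.19 ± 0.24, limma adjusted p = 0.0385). Cyp8b1, the sterol 12-alpha-hydroxylase of cholic acid synthesis, stood at 11.5 and 11.8 in WT and at 10.8 in both Baf60a LKO arrays (-0.80 ± 0.14, adjusted p = 0.153). Cyp7a1, the rate-limiting enzyme of the classical pathway, differed by -0.14 ± 0.18, and by 0.08 without WT replicate 2, and Cyp27a1 differed by -0.26 ± 0.11, neither past the threshold. Of the 18 measured members of the list, 0 rose, 1 fell and 17 did not pass, and 2 fell when adjusted over the list alone. The list was shifted lower, with a median of -0.19 (camera, adjusted p = 0.00806), and had adjusted p = 0.632 with an estimated correlation. Without WT replicate 2 and without Baf60a LKO replicate 1 the camera value was 0.0971 and 0.0810, and leaving out 1 array gave medians of -0.23 to -0.12.

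Of the 14 bile acid transporters, Slco1a4 and Abcc3 fell, the latter, a basolateral exporter, 2.02-fold (log2 fold change -1.02 ± 0.12, limma adjusted p = 0.0444), and 12 did not pass. Abcb11, the canalicular bile salt pump, differed by -0.07 ± 0.11 and Slco1a1 by -0.98 ± 0.18 (adjusted p = 0.155). Adjusted over the list alone, 3 fell and 2 were higher. The list did not pass (camera, adjusted p = 0.241). Among the 12 genes of bile acid sensing and its regulators, Nr1i3 was the 1 that fell and 11 did not pass. Nr1h4, the bile acid receptor FXR, differed by 0.23 ± 0.12, its target Nr0b2 by 0.06 ± 0.14 (below 0 after quantile or loess normalization) and Fgfr4 by 0.57 ± 0.15 (0.08 with averaged probe sets). That list had a positive median of 0.13 and a negative mean of -0.28 and did not pass (adjusted p = 0.825).

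**Figure D2:**
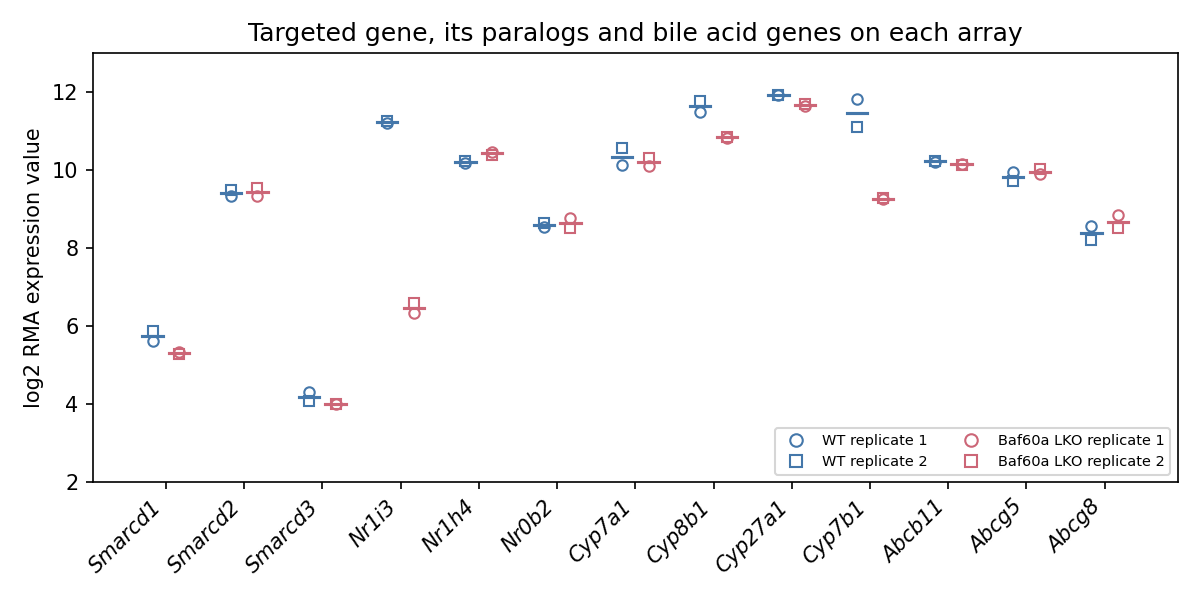
The y axis gives the log2 RMA value on each of the 4 arrays for 13 genes on the x axis, with circles for replicate 1, squares for replicate 2 and a line at the mean of the 2 arrays of a group. Nr1i3 (11.2 in WT, 6.46 in Baf60a LKO) and Cyp7b1 (11.5 and 9.27) lie far apart between groups, while Cyp7a1 overlaps (10.3 and 10.2).

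Cholesterol synthesis genes, the targets of SREBP-2, lay slightly lower in Baf60a LKO livers, 14 of 20, while those of cholesterol transport did not pass as a list. The other 6 were higher, among them Dhcr7 by 0.44 ± 0.16, chosen after its values were seen. Of the 20, 0 passed over all genes and 5 fell when adjusted over the list alone. Fdps differed by -1.14 ± 0.18, Hmgcs1 by -0.95 ± 0.19, Idi1 by -0.86 ± 0.24 (-0.54 without Baf60a LKO replicate 2) and Cyp51 by -0.82 ± 0.20. With averaged probe sets Fdps and Cyp51 were at -0.59 and -0.53. The list median was -0.19 (camera, adjusted p = 0.00370), and the list had adjusted p = 0.832 with an estimated correlation. Without WT replicate 2 and without Baf60a LKO replicate 2, camera gave 0.505 and 0.0719. The median ran from -0.36 without WT replicate 1 to -0.14 without Baf60a LKO replicate 2, and was -0.11 with averaged probe sets and -0.10 without _x_at and _s_at probe sets. Of 26 genes of cholesterol transport and lipoproteins, Vldlr, a receptor for triglyceride-rich lipoproteins, rose 3.16-fold (log2 fold change 1.66 ± 0.18, limma adjusted p = 0.0387, but 0.96 with adjusted p = 0.103 without _x_at and _s_at probe sets) and 25 did not pass, with 2 higher over the list alone. Apoc2 differed by 0.79 ± 0.13, and Abcg5 and Abcg8, the sterol exporters, by 0.13 ± 0.14 and 0.29 ± 0.18. The values of Abcg5 and Abcg8 were 0.0022 and 0.12 without WT replicate 2, and 0.25 and 0.46 without WT replicate 1. The transport list did not pass (camera, adjusted p = 0.269).

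Target genes of CAR and the related receptor PXR lay lower in Baf60a LKO livers, 18 of 21. Of these 21 measured members, 4 fell (Cyp2c50, Cyp2c54, Cyp2c37 and Abcc3), 0 rose and 17 did not pass, and 11 fell when adjusted over the list alone. The median was -0.76 (camera, adjusted p = 2.75e-11), and the list had adjusted p = 0.632 with an estimated correlation. Genes expressed near the central vein shared 2 of these members, Cyp2c50 and Cyp2c37, the 2 that fell among 15, and 4 fell over the list alone. Other pericentral genes were Lgr5 (-0.80 ± 0.17, and -0.42 with averaged probe sets) and Cyp1a2 (-0.47 ± 0.12), neither past the threshold. The pericentral median was -0.32 (camera, adjusted p = 0.000112), and that list had adjusted p = 0.632 with an estimated correlation and 0.165 by camera without WT replicate 2. Among 13 periportal genes, Cyp2f2 fell 3.53-fold and 12 did not pass, 2 fell over the list alone, and the list did not pass (camera, adjusted p = 0.880). Its median was 0.05 and its mean -0.11.

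Genes expressed more in male than in female mouse liver lay lower as a list in Baf60a LKO, though members went both ways, 9 lower and 6 higher. Of the 15, 6 fell over all genes and 9 did not pass. Hsd3b5, Serpina12 and Serpina4-ps1 were among the 6, as were Cyp7b1, Mup3, which fell 9.34-fold (log2 fold change -3.22 ± 0.21, limma adjusted p = 0.0116, and -2.11 with averaged probe sets), and Cyp4a12a, which fell 2.91-fold and was chosen after its values were seen. Adjusted over the list alone, 8 fell and 1 was higher. The median was -0.98 (camera, adjusted p = 3.16e-05), and the list had adjusted p = 0.632 with an estimated correlation. Of 14 female-biased genes 0 passed, and 2 fell when adjusted over the list alone. Cyp2b9, which the CAR and PXR list also holds, stood at 10.9 and 9.22 in WT and differed by -4.34 ± 0.68 (limma, adjusted p = 0.113). The female-biased list did not pass (camera, adjusted p = 0.314).

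Lipid droplet genes and targets of PPARgamma lay lower as a list in Baf60a LKO livers, 12 of 14. Pparg itself fell 4.79-fold (log2 fold change -2.26 ± 0.18, limma adjusted p = 0.0181), and the droplet protein gene Plin4 fell 6.74-fold. Mogat1, an enzyme of triglyceride synthesis, fell 3.79-fold, Cidea at least 2.59-fold (near background in Baf60a LKO) and Fitm1 2.18-fold, the last chosen after its values were seen. Of the 14, these 5 fell and 9 did not pass, and 6 fell over the list alone. The median was -0.46, and -0.74 to -0.30 with 1 array left out (camera, adjusted p = 1.01e-08), and the list had adjusted p = 0.632 with an estimated correlation. Adipocyte markers shared 2 genes with this list. Of 7 measured, all were lower, 1 fell (Car3, 2.36-fold, log2 fold change -1.24, adjusted p = 0.0321, and -2.34 with averaged probe sets) and 2 fell over the list alone. Their median was -0.40 (camera, adjusted p = 0.00120), but -0.09 without WT replicate 1, -0.72 without WT replicate 2 and -1.11 over the 3 in the brighter 50% of genes, and they had adjusted p = 0.632 with an estimated correlation. Car3 read 13.4 and 13.5 in WT, while Ucp1 (2.82 to 3.63 over the 4 arrays) and Retn (4.09 to 4.85) were dim. Whether these markers report adipocytes in the samples was not tested. Mogat1 was also the 1 gene that fell among 23 genes of fatty acid and triglyceride synthesis, and Cyp4a14, 4.20-fold lower, the 1 among 25 genes of fatty acid oxidation and PPARalpha targets. Each was also the 1 that fell adjusted over the list alone, and camera gave adjusted p of 0.944 and 0.940 for these 2 lists.

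Interferon-stimulated genes lay lower in Baf60a LKO, 22 of 24, though none passed over all genes. Gbp6 differed by -1.29 ± 0.22, Ifit1 by -1.21 ± 0.18, Ifit3 by -0.73 ± 0.15 and Usp18 by -0.67 ± 0.18. Adjusted over the list alone, 7 fell. The median was -0.31 (camera, adjusted p = 4.45e-07), and the list had adjusted p = 0.632 with an estimated correlation. Of 25 acute phase genes and NF-kB targets, Saa1 and Saa2 rose and 23 did not pass, with 3 higher over the list alone. Orm2 stood at 7.03 and 7.72 in WT and at 9.62 and 11.3 in Baf60a LKO (limma, adjusted p = 0.156). Lcn2 differed by 1.29 ± 0.68, with overlapping groups, by 0.27 without Baf60a LKO replicate 2 and by 2.31 without Baf60a LKO replicate 1. The acute phase list did not pass (camera, adjusted p = 0.186).

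Markers of cholangiocytes, the cells that line bile ducts, lay higher in Baf60a LKO, with a median of 0.38 over 11 genes. None passed over all genes, and over the list alone 5 were higher and 1 lower. Pkhd1 differed by 1.34 ± 0.30, Epcam by 1.17 ± 0.21 (0.40 with averaged probe sets), Cldn7 by 0.89 ± 0.16 and Krt23 by -0.47 ± 0.12. Camera gave adjusted p = 0.0204, the list had adjusted p = 0.632 with an estimated correlation, and camera gave 0.302 without WT replicate 2. The median was 0.21 to 0.48 with 1 array left out and 0.18 over the 4 markers in the brighter 50% of genes. Of 19 clock genes, 14 were higher, with a median of 0.17, and none passed over all genes or over the list alone. Per2 differed by 0.53 ± 0.21 (0.32 without WT replicate 1 or without Baf60a LKO replicate 2) and Per3 by 0.39 ± 0.12. Camera gave adjusted p = 0.0479, close to the threshold, and 0.832 with an estimated correlation. The list missed the threshold under 9 of 12 other settings, among them the 3 other normalizations (0.0592 to 0.142, with a median of 0.10 after loess) and 3 of the 4 with 1 array left out (0.0638 to 0.348), where the median was 0.10 to 0.27.

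**Figure D3:**
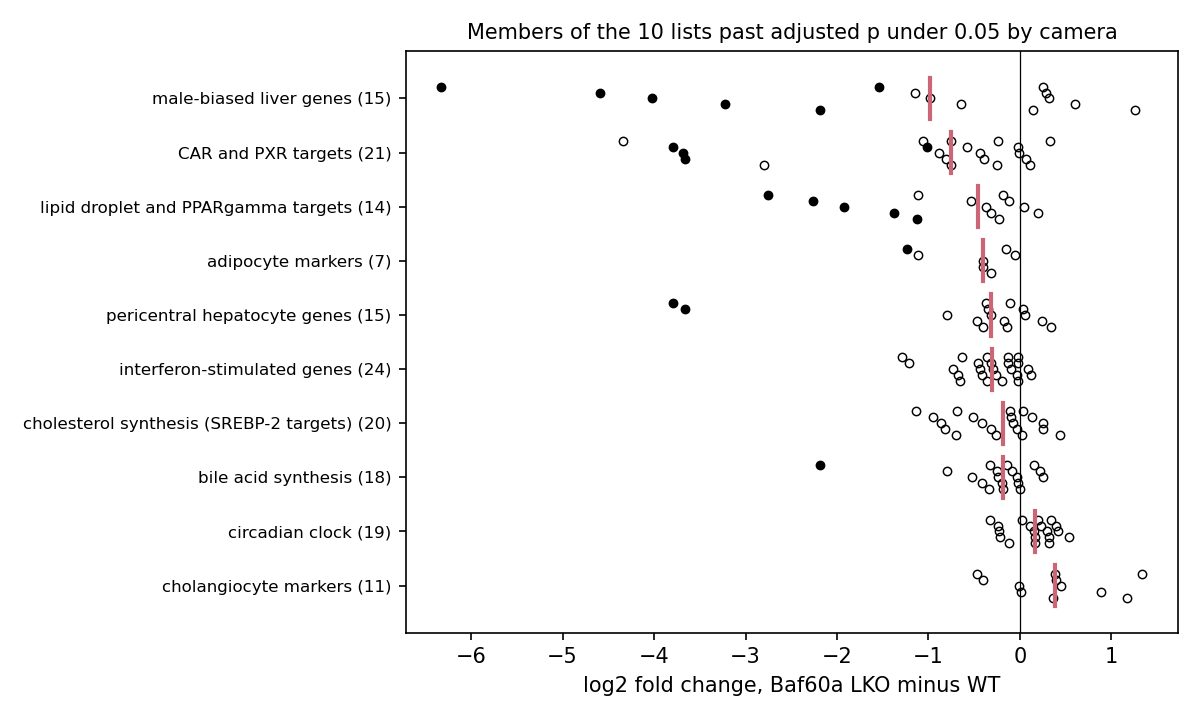
The x axis gives the log2 fold change, Baf60a LKO minus WT, of each measured member of the 10 lists past adjusted p under 0.05 by camera, with list sizes in brackets. Filled points passed over all genes by limma, open points did not, and the bar is the list median, from -0.98 for male-biased genes to 0.38 for cholangiocyte markers.

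Camera placed 10 of 39 lists past the threshold, 8 lower and 2 higher, and 0 passed with an estimated correlation (lowest unadjusted p 0.0613) or by fry (10 at an unadjusted p under 0.05). For bile acid synthesis and adipocyte markers the estimated correlations, -0.00398 and -0.118, lay below the preset 0.01. Their unadjusted camera p still rose, from 0.00165 to 0.0765 and from 0.000185 to 0.0613. Camera with an estimated correlation has 2 residual degrees of freedom, so missing the threshold does not show that correlation explains a shift. Among lists not yet named, 1 of 15 NRF2 targets fell, the carboxylesterase gene Ces1g, 5.51-fold, with 3 lower and 1 higher adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.249). No gene passed over all genes in the lists for gluconeogenesis and fasting (adjusted p = 0.825) or oxidative phosphorylation (0.835). The same held for MHC class II (camera, adjusted p = 0.0562), complement and coagulation (0.944), unfolded protein response (0.825), heat shock and immediate early genes (0.663), cell cycle (0.0562), fetal liver and injury genes (0.212) and extracellular matrix (0.370). Markers of hepatocytes (camera, adjusted p = 0.859), Kupffer cells (0.880), endothelium (0.241), stellate cells (0.825), T and NK cells (0.880) and B and plasma cells (0.241) did not pass. Nor did those of neutrophils (camera, adjusted p = 0.825), erythroid cells (0.241), pancreas acini (0.825) and skeletal muscle (0.0562). Adjusted over the list alone, 4 fetal liver and injury genes, 3 cell cycle genes and 1 heat shock or immediate early gene were lower, 1 matrix gene and 1 neutrophil marker were higher, and 1 unfolded protein response gene went each way. The other lists of this paragraph had 0. Median and mean had opposite signs for gluconeogenesis, fatty acid oxidation, unfolded protein response, hepatocyte, T and NK cell and neutrophil genes, and for Kupffer cell markers both were positive while camera pointed lower. Of 4 sex chromosome genes, too few for a test, none passed. Over the 4 arrays the Y-linked Eif2s3y read 7.49 to 8.22 and Kdm5d 5.91 to 6.13, while the X-linked Xist read 3.29 to 3.74. Baf60a LKO differed from WT by 0.30 ± 0.22, -0.11 ± 0.12 and -0.01 ± 0.18 for these, and by 0.46 ± 0.14 for the Y-linked Uty. These values argue against a difference in sex between the groups as the reason for the lower male-biased genes.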

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

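All tests in this part were chosen after the values were seen. Probe sets for the phage P1 Cre recombinase, which the array carries as controls and which no comparison above uses, read higher in both Baf60a LKO arrays than in both WT arrays. The log2 differences were 3.41 ± 0.18 for AFFX-r2-P1-cre-3_at, 2.08 ± 0.18 for AFFX-CreX-3_at, 1.26 ± 0.17 for AFFX-r2-P1-cre-5_at and 0.65 ± 0.15 for AFFX-CreX-5_at, and the first 2 of these 4 passed by limma over 45101 probe sets, controls included. Hybridisation controls added to the Baf60a LKO samples alone are argued against by the bioB, bioC and bioD probe sets of the same mix. These 14 had differences of -0.36 to 0.01, with a median of -0.20. Most lay near background: AFFX-BioDn-3_at read 5.47 to 5.91 over the 4 arrays, and the other bio probe sets 3.42 or lower. No array of either group thus shows the mix clearly. A Cre transgene expressed in the Baf60a LKO livers stays open, since the count of 3 of 4 Cre probe sets past the threshold or higher by over 1 in both arrays only restates the pattern, and the labels used here do not say how the gene was deleted.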

How the results depend on the processing

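All 88 called genes kept their direction in every alternative that measured them, but in several of these it could not turn. The groups of all 88 did not overlap, so leaving out 1 array cannot change a sign. The brighter genes, the trended and robust eBayes, the replicate block and other thresholds leave the fold changes as they were. Direction was thus tested only by the further normalizations, averaged probe sets and leaving out _x_at and _s_at probe sets. The count of called genes depended on the setting. It was 113 after quantiles, 142 after cyclic loess (72 higher, 70 lower), 154 with array medians subtracted (91 higher, 63 lower), 216 with a trended and robust eBayes (118 higher, 98 lower), and 92, 95 and 80 for the brighter genes, averaged probe sets and no _x_at or _s_at. At adjusted p under 0.1 there were 125 (68 higher, 57 lower). Without 1 array, 0 to 17 genes passed (0 to 3 higher, 0 to 14 lower), with 0 of the 88 kept without WT replicate 1, and limma passed 0 probe sets under each (1196 to 10697 at an unadjusted p under 0.05). Probe sets past the threshold numbered 84, and 139, 162, 146 and 173 after quantiles, loess, medians and the trended eBayes, and 143 at adjusted p under 0.1. The cause was not tested, except that 1 array fewer leaves fewer degrees of freedom. Replicate numbers did not pair the samples by the labels (correlation over genes of the deviations of same-numbered samples from their group means, 0.143). A replicate block gave 19 genes (5 higher, 14 lower) and 4 probe sets. Lists past the threshold numbered 8 to 13, but 0 with an estimated correlation and 0 by fry. The brighter genes left too few cholangiocyte (4) and adipocyte (3) markers for camera. Of the 29 lists that did not pass, 17 changed camera's direction under at least 1 setting and 8 passed under at least 1. None of the named genes whose sign turned had passed: Smarcd2 (-0.0089 after quantiles, -0.0395 after loess, -0.0857 with averaged probe sets, -0.0764 to 0.1376 without 1 array), Nr0b2 (-0.0038 after quantiles, -0.0231 after loess, -0.0651 to 0.1838 without 1 array), Ss18l1 (0.18 without _x_at or _s_at), Cyp7a1 (-0.3642 to 0.0785 without 1 array) and Cyp2c70 (-0.882 to 0.0446 without 1 array). Genes near the bacterial background (medians of 2.30 to 2.50, 95th percentiles of 3.02 to 3.42) have folds that the signal limits.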

Other observations

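Of the tests in this part, those of chance position, of the Nr1i3 surroundings and of WT replicate 1 were chosen after values were seen; that of the other Tomm40l probe set was set before its result was known, though the calls around Nr1i3 were known by then. Outside every list lay 64 of the 88 called genes, 40 higher and 24 lower in Baf60a LKO. Those named here were chosen after their values were seen. Cdh1, the gene of E-cadherin, rose 2.68-fold (log2 fold change 1.42 ± 0.14, limma adjusted p = 0.0293), the integrin gene Itga6 rose 2.33-fold and the membrane protease gene Prss8 rose 2.03-fold. Wfdc2 rose 2.96-fold while Wfdc21 fell 5.96-fold. Among single transporter genes, Slc3a1 rose 3.30-fold and Slc25a4 rose 3.08-fold, while the zinc transporter gene Slc39a4 fell 5.89-fold and Slc17a1 fell 4.87-fold. Transporter genes outside the lists were not counted as a group.

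Gene families were taken by symbol after the values were seen, and camera was run on 19 of them, but its p-values are left out because the choice followed the calls. Of the 11 Cyp2c genes, 3 fell, and their median was -0.76. Of 13 sulfotransferases (Sult), with a median of -0.19, 1 fell, Sult5a1, 9.50-fold, and Sult1b1 stood 2.96-fold lower (limma, adjusted p = 0.0501). Of 21 glutathione S-transferases (Gst), 1 rose, Gstp3, and 0 fell, while the median was -0.24, with Gsta2 at -1.48 ± 0.26 and Gstt3 at -1.25 ± 0.22.

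Nr1i3 fell 27.3-fold while the genes on either side of it, Pcp4l1 and Tomm40l, rose 6.11-fold and 3.87-fold. Of 10000 random draws of 88 genes, 16, a share of 0.0016, held a run of 3 adjacent genes of different families. This measure was set with the run in view, and the draws treat genes as independent. It therefore does not decide whether the called genes lie together by chance. A faulty Tomm40l probe set is argued against by the other one, which rose by 2.91 on the log2 scale. Of the 18 measured genes around Nr1i3 beyond the nearest, 0 passed by limma, with 3 at an unadjusted p under 0.05. An altered Nr1i3 locus in the Baf60a LKO mice (0 of those 18) and an effect of BAF60a loss on this stretch of chromatin could not be told apart, since every Baf60a LKO array shows the pattern and no sequence was analysed here.

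WT replicate 1 stood apart from the other arrays. Of the 30 genes with the largest difference between the WT arrays, it lay below all other arrays for 20, above all for 7 and within their range for 3. Among these, chosen for the difference, Micu3 read 3.05 against 4.36 to 4.64, Frk 3.14 against 4.38 to 4.64 and Cyp2b13 5.67 against 3.44 to 3.65, while for Ppp1r3g it was WT replicate 2 that stood apart, at 6.42 against 3.90 to 4.31. The mean 3' minus 5' difference of 3 control transcripts lay -0.0116 from that of the other arrays. This mean joins opposite shifts, so it does not decide whether the RNA was degraded. For Gapdh, WT replicate 1 read 0.0653 against -0.0212 to 0.0212 on the other arrays, and for pyruvate carboxylase 6.718 against 6.724 to 6.889. For actin it lay within their range, at 0.742 against 0.722 to 0.761. A different distribution of values on the array is argued against as the whole cause, because the standard deviation of the WT difference was still 1.46 times that of the Baf60a LKO difference after quantile normalization, against 1.55 times as deposited. WT replicate 1 also had the highest median of the bacterial probe sets, 2.50 against 2.30 to 2.36 on the other arrays. Its 25th percentile was 3.09 against 2.93 to 2.95, and its 75th percentile 6.26 against 6.44 to 6.47. Whether its difference lies in the array, in the quality of the RNA or in the mice of the pools stays open and was not settled by these tests.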
